A study of Mus musculus with 19 samples.

How the data were processed

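Total RNA from sorted C57BL/6 mouse bone marrow progenitors was isolated with RNeasy plus micro columns and turned into libraries with the SMARTer Ultra Low v3 and Nextera XT kits, per the labels' protocols. These kits do not mark the strand of a transcript. The 19 libraries were grouped by their titles into ALP (7), EILP (7) and ILCp (5), and the labels place them in 5 sequencing batches, of which batch 3 holds EILP alone (2 libraries) and batch 5 no ILCp. Names in the submitters' processing notes are bcl2fastq 1.8.4, STAR 2.4.0h, edgeR, limma and the mouse build mm10, with no role or order given, and the annotation and counting method are not given in the sources used here.

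The deposited table holds log2 values for 18607 genes in 19 libraries, with 9 empty columns and no unused column of samples. From the values, these deposited log2 numbers are log2 CPM brought to a common distribution and then cleared of batch differences while keeping the 3 groups. The sum of 2 to the power of the values was 908573 to 1035200 per library, and between 34.9% and 61.8% of the levels in a library were shared with others, against at most 1.71% by chance. The largest batch coefficient next to the groups was 1.15e-08, against 5.14 for batch alone, and 2423 of 2426 genes with a zero level in all 5 batches had 1 common mean level of −4.96 (tolerance 1e-05). No header or label records these steps. Removing batch in this way leaves the fold changes of a model with batch as they are, makes the SD within groups too small, and gives a model without batch 16 residual degrees of freedom in place of 12. Total counts per library are unknown, so no counting interval was computed. Pairwise correlations of the libraries over genes with a mean above 2 log2 CPM ranged from 0.376 to 0.904, and principal components 1 and 2 held 22.3% and 14.2% of the variance.

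Before the data were examined, the tests, the named-gene rule, the 23 gene lists and the other settings to be tried were fixed. Genes were compared with limma 3.58.1 in R 4.3.3 (moderated, with a mean-variance trend, two-sided) on the values as deposited, with all 19 libraries, the groups and batch as a fixed effect, and Benjamini-Hochberg adjusted p below 0.05. With batch in the model, the 2 EILP libraries of batch 3 inform the errors but not the fold changes. Fold changes were the same without batch 3, as in Ltb (5.98, ILCp versus EILP). The reporter strains were compared in the same model with ILCp divided into 3 Tcf7EGFP and 2 Plzf-cre-GFP libraries. Errors of fold changes are standard errors of this model, and errors of levels are SDs over libraries. Gene lists with at least 3 members were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated per list, and with fry, adjusted over the 23 lists. They covered sorting markers, innate lymphoid transcription factors, lymphoid and stem progenitor genes, genes of other lineages, and genes of receptors, cell cycle, stress, interferon, metabolism, apoptosis, ribosomes and mitochondria.

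The rule for named genes took 17 fixed genes of innate lymphoid development and sorting, up to 2 rising and 2 falling members of each list with the smallest p, the 5 largest increases and decreases among genes above the median level in their higher group with the same sign in every batch, and the 5 leading genes of the EILP and reporter patterns. Dntt, Lef1, Eomes, Icos, Ltb, Mpo and Arg1, and the marker genes of other cell types, fell outside it and were chosen after their values were seen. Of the genes the rule took, 2 are not reported here. A gene was taken as at the zero level in a group by the libraries of batches holding at least 2 libraries of that group. These were 5 ALP, 4 EILP and 3 ILCp libraries, and the gene had to lie at the batch's zero level in each.

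The other settings were no batch term, the replicate number as a block, batch as a random effect, only the groups compared, only batches with both groups, batch 5 alone, no Plzf-cre-GFP libraries, each library left out, a fold change of at least 2 (1 on the log2 scale), quantile normalization, median centring, the upper part of genes by mean level, and limma without trend or with robust variance. A pseudocount does not apply to values deposited as logs. Alternatives without ALP 7 and EILP 2 together, without batch 3 and without batch 4, and the lists without the sorting markers, were chosen after seeing the data. The procedure was tested on simulated data with 200 changed genes among 18607 in 10 draws. At log2 changes of 1, 2 and 4 it recovered 12.8%, 39.1% and 63.8% for EILP versus ALP, 10.4%, 30.1% and 59.2% for ILCp versus EILP and 12.1%, 35.1% and 61.2% for ILCp versus ALP, with 7.51%, 4.73% and 6.09% of calls false. A raised list was called in 10 of 10 draws of each comparison, and 0 of 220 random lists. Groupings of the real libraries were redrawn 100 times, the real one included. In the 99 others the same list test passed a median of 3 of the 23 lists for EILP versus ALP, 4 for ILCp versus EILP and 3 for ILCp versus ALP, and at least 1 list in 88, 95 and 88 of them. The simulated genes were drawn independently, so the 0 of 220 does not give the rate of chance calls at the preset correlation in these libraries. The redrawn groupings divide the real groups unevenly and can carry real differences, so their counts do not give that rate either.

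Symbols were matched to GENCODE M21 (GRCm38) for coordinates: 17377 of 18607 (93.4%) matched, 19 more were found in RefSeq and 1211 in neither. Of 181 genes looked up, 180 had 1 position, and 53 overlapped a gene on the other strand. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.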

Results

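RNA-seq libraries were made from 19 samples of lymphoid progenitors sorted from the bone marrow of C57BL/6 mice. The 3 stages sampled lead towards innate lymphoid cells (ILC), the tissue-resident lymphocytes that lack rearranged antigen receptors. The earliest stage was ALP, lineage-low progenitors with Kit, IL-7Rα and high Flt3 on their surface and low Ly-6D (7 libraries). EILP were early innate lymphoid progenitors with Kit, high green fluorescence, low CD122 and Thy-1.2 and intermediate to low IL-7Rα (7 libraries). ILCp were later ILC progenitors with Kit, high green fluorescence, Thy-1.2, α4β7 integrin and high IL-7Rα (5 libraries). The fluorescence reported Tcf7 in mice with a Tcf7EGFP allele (Tcf7EGFP/+), except in ILCp 4 and ILCp 5, which came from mice with a Plzf-cre-GFP allele (Plzf-cre-GFP/+). Libraries belonged to 5 sequencing batches. EILP 3 and EILP 4 alone made up batch 3. With batch in the model they bear on the errors and not on the fold changes. All values below are the authors' log2 CPM (read counts scaled to library size). From the values, these had been brought to a common distribution and cleared of batch before deposit. An SD of these values therefore leaves out the spread between batches. The table holds 18607 genes and no counts, and the depth of each library is unknown. The lowest level above zero ranged from 0.00270 CPM in EILP 5 and ILCp 5 to 0.746 CPM in ALP 7. Such a level can recur in several libraries, as in EILP 5 and ILCp 5, so it is not the detection limit of a library. The share of 4568 rarely detected genes that lay at zero ranged from 64.2% in ILCp 5 to 92.4% in ALP 7. A low transcript could therefore be missed in some libraries and seen in others. A fold change against libraries at the zero level (−4.96 log2 CPM on average) depends on that level. No fold is given below where the lower group lay at the zero level in each of its libraries that shared a batch with another of the same group. The rank of such a gene among the largest changes depends on that level too. Other folds can still rest in part on the zero level. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

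The sorting markers were read first as a check of the labels. Tcf7, which carries the reporter and encodes the transcription factor TCF-1 (chromosome 11, 52252371 to 52283014, GRCm38), was at 1.06 ± 2.64 log2 CPM in ALP (SD, n = 7), 10.51 ± 1.85 in EILP (n = 7) and 9.24 ± 0.28 in ILCp (n = 5). Il7r, the IL-7 receptor α chain (chromosome 15, 9505788 to 9530176), was at 7.46 ± 0.78, 5.34 ± 0.89 and 9.93 ± 0.37 in the same order. Flt3 was at 10.21 ± 0.69, 7.34 ± 0.55 and 3.25 ± 3.83. Thy1 was at −2.84 ± 1.16, 0.07 ± 0.94 and 5.30 ± 0.83. Il2rb, the CD122 gene, was at −1.68 ± 2.88 in ALP and 7.14 ± 1.57 in EILP (limma adjusted p = 0.000346). Thus Il2rb and Thy1 RNA rose from ALP to EILP, although the EILP gate took low CD122 and Thy-1.2 on the surface. From ALP to EILP, 6 of the 9 sorting markers rose and 1 fell (limma camera adjusted p = 0.000505, adjusted p = 0.0421 with an estimated correlation). Adjusted over the list alone, 6 rose and 3 fell. From EILP to ILCp, 3 rose, with 3 higher and 1 lower adjusted over the list alone. The list did not pass (limma camera adjusted p = 0.131). Because these genes were used in the gate of at least 1 of the groups, their levels are not taken as findings. They are also members of other lists: Tcf7 of the innate lymphoid factors, Flt3 of the lymphoid progenitor genes, Ly6d of the B lineage genes, Il2rb, which encodes CD122, of the NK cell and ILC1 genes, Itga4 and Itgb7 of the chemokine receptor and adhesion genes, and Il7r, Kit, Flt3 and Il2rb of the cytokine receptor genes. The lists were tested again without them, an alternative chosen after seeing the data, and its values are given where a call changed or where sorting markers made up several of the genes counted.

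The comparison of EILP with ALP addressed which transcripts differ at the first step towards the innate lymphoid lineage. Transcription factors of innate lymphoid development were the leading group. Of 14 such genes, 11 rose, 1 fell and 2 did not pass, with the same numbers adjusted over the list alone. Their median log2 fold change was 5.07, with a limma camera adjusted p of 6.32e-23 (adjusted p = 0.000176 with an estimated correlation). Genes of the lymphoid progenitor state moved the other way, with 11 of 16 lower and 1 higher (limma camera adjusted p = 2.34e-12, adjusted p = 0.0108 with an estimated correlation), or 15 lower and 1 higher adjusted over the list alone.

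Among the factors, Nfil3, a basic leucine zipper protein needed to form ILC progenitors (chromosome 13, 52967209 to 52981073), rose by 2.96 ± 0.34 (SE) on the log2 scale to 8.19 ± 0.09 in EILP (limma adjusted p = 4.53e-05). Tox (chromosome 4, 6686353 to 6991557) and Tox2 (chromosome 2, 163203125 to 163324170), related HMG-box proteins, rose by 4.17 ± 0.24 and 10.98 ± 0.76. Id2, which blocks E proteins (chromosome 12, 25093799 to 25097140), rose by 4.58 ± 0.23 (limma adjusted p = 1.09e-08). Gata3 (chromosome 2, 9857078 to 9890034), which ILC2 and T cells require, rose by 5.55 ± 0.39 from 1.55 ± 0.73 in ALP. Zbtb16, which encodes PLZF (chromosome 9, 48654297 to 48836222), rose by 9.37 ± 0.95. The nuclear receptor gene Rora (chromosome 9, 68653786 to 69388246) rose by 7.33 ± 0.94 (limma adjusted p = 0.000144). Bcl11b, a zinc finger factor of T cells and ILC2 (chromosome 12, 107910403 to 108003602), was at the zero level in ALP and at 4.39 ± 0.34 in EILP. Lef1, a relative of Tcf7, was likewise at the zero level in ALP and at 4.55 ± 0.67 in EILP. Ets1 (chromosome 9, 32636221 to 32757820) was the member that fell, by 1.76 on the log2 scale, to 5.50 ± 0.68 (limma adjusted p = 0.00865).

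**Figure D1:**
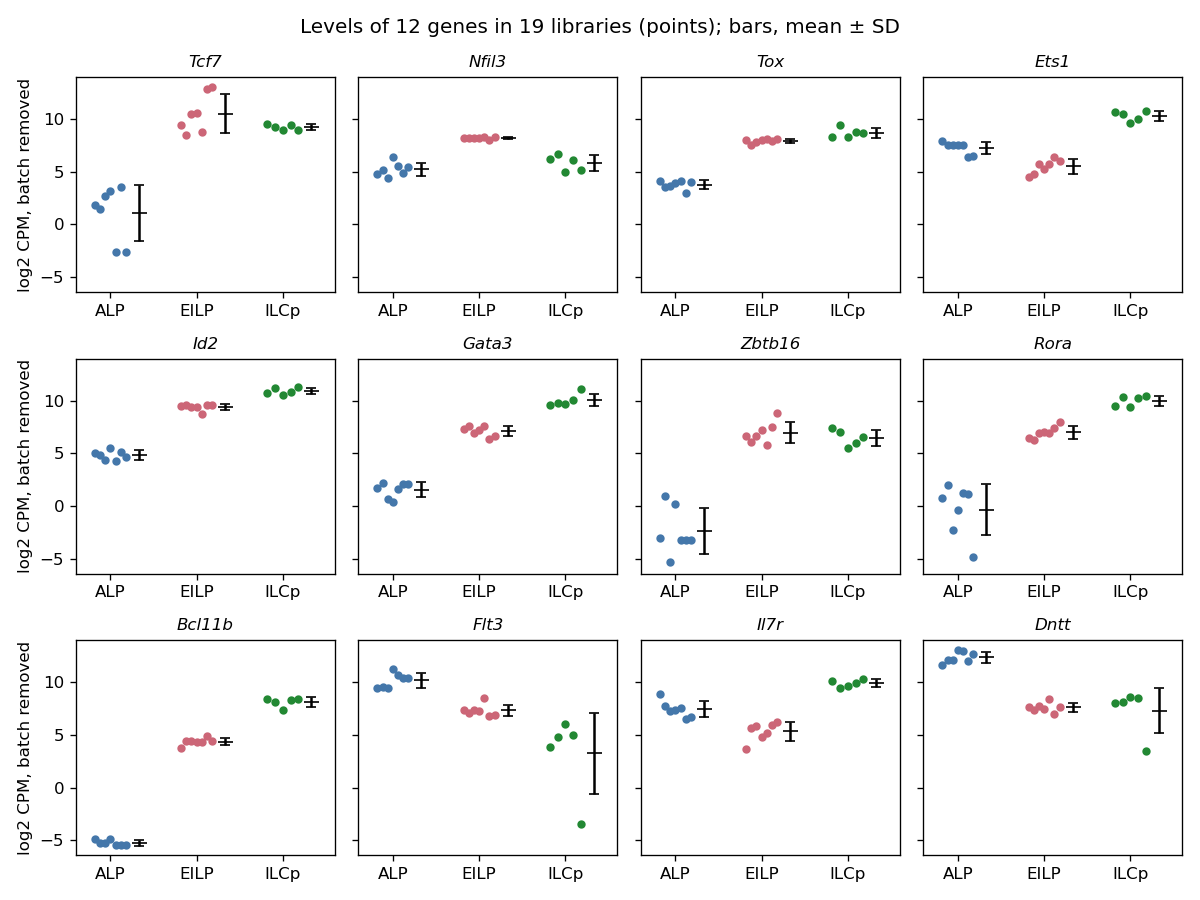
Levels of 12 genes (vertical axis, log2 CPM with batch removed) in each of the 19 libraries (points) of ALP, EILP and ILCp, with the mean and SD of each group as bars. Id2 and Gata3 stepped upward at both transitions, Nfil3 peaked in EILP at 8.19, and Ets1 and Il7r were lowest in EILP.

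Genes of the lymphoid progenitor list that fell included Dntt, the template-free DNA polymerase of antigen receptor joining, which changed by −4.76 ± 0.70 from 12.38 ± 0.53 in ALP. Rag1, the recombinase (chromosome 2, 101638282 to 101649501), changed by −7.04 ± 1.53 (limma adjusted p = 0.0111). Notch1 changed by −2.19 ± 0.31 and Cd93 by −1.59 ± 0.22. Ikzf2, which encodes Helios, was the member that rose, by 3.32 ± 0.72. In the stem and multipotent progenitor list 3 of 12 fell and none rose (5 lower adjusted over the list alone, limma camera adjusted p = 9.18e-05, adjusted p = 0.0421 with an estimated correlation). Ly6a, which encodes Sca-1, changed by −3.43 ± 0.47. Of 15 B lineage genes 4 fell and none rose, or 6 lower adjusted over the list alone (limma camera adjusted p = 5.00e-05, adjusted p = 0.157 with an estimated correlation). The Src-family kinase gene Blk changed by −7.78 ± 1.47, and Vpreb2, the surrogate light chain, was at −0.17 ± 2.13 in ALP and at the zero level in EILP. Interferon-stimulated genes were lower too, with 4 of 14 down and none up, or 7 down adjusted over the list alone (limma camera adjusted p = 1.32e-08, adjusted p = 0.0108 with an estimated correlation). Irf7, the interferon regulatory factor, changed by −1.59 ± 0.21 and Ifi44 by −7.10 ± 0.99 (limma adjusted p = 0.000309). The cell cycle list fell slightly, with a median of −0.38, 6 of 23 members lower and 11 lower adjusted over the list alone (limma camera adjusted p = 1.14e-06, adjusted p = 0.0523 with an estimated correlation). The mitotic kinase gene Cdk1 changed by −0.80 ± 0.16 and Cdc20 by −0.76 ± 0.16.

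The lists of NK cell and ILC1, ILC2 and T lineage genes passed upward, of which the NK cell and ILC1 list alone also passed with an estimated correlation. In the NK cell and ILC1 list 7 of 17 were higher and none lower, 9 adjusted over the list alone (limma camera adjusted p = 1.04e-07, adjusted p = 0.0108 with an estimated correlation). The chemokine gene Ccl5 rose by 9.05 ± 0.83 to 6.78 ± 0.48, and the granule gene Nkg7 by 1.48 ± 0.20. The T-box factor gene Eomes was at 1.95 ± 2.48 in EILP and at the zero level in ALP. Of 14 ILC2 genes 5 rose, also 5 adjusted over the list alone (limma camera adjusted p = 0.000266, adjusted p = 0.0867 with an estimated correlation). The list's median was 0.07 and its mean 2.29. Il1rl1, the IL-33 receptor of ILC2, was at −0.85 ± 2.24 in EILP and −0.08 ± 2.92 in ALP (limma adjusted p = 0.841). Of 16 T lineage genes 3 rose, with 6 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.00511, adjusted p = 0.257 with an estimated correlation). Themis, a T cell signalling adaptor, was at 4.89 ± 0.74 in EILP and at the zero level in ALP. Trat1, which associates with the T cell receptor, rose by 5.79 ± 0.90. The chemokine receptor gene Cxcr5 rose by 7.26 ± 0.86. Tbx21, which encodes T-bet, was at −2.62 ± 2.64 in EILP and −5.96 ± 2.35 in ALP (limma adjusted p = 0.277).

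The 5 largest increases among well expressed genes were in Rxrg, a retinoid X receptor (chromosome 1, 167598384 to 167639623), Fgf3, a growth factor, Tox2, and the T cell receptor constant genes Trbc1 (chromosome 6, 41538218 to 41539881) and Tcrg-C4 (chromosome 13, 19344558 to 19352756). Trbc1 rose by 11.19 ± 0.84 to 7.69 ± 0.26 in EILP (limma adjusted p = 5.78e-07). Rxrg reached 6.20 ± 0.70, Fgf3 7.25 ± 0.76 and Tcrg-C4 6.10 ± 0.54, each from the zero level in ALP. In the same EILP libraries the T cell receptor complex genes Cd3d, Cd3e, Cd3g, Cd5 and Trac averaged between −3.53 (EILP 6) and 2.22 (EILP 7). Among the 5 largest decreases were Gfra1, a receptor of glial growth factors (chromosome 19, 58235604 to 58455909, −10.11 ± 0.98), and the cytochrome gene Cyp2j6 (−9.97 ± 1.10). The others were the ADP receptor gene P2ry13 (−9.81 ± 1.47), the RNA helicase gene Ddx4 (−9.65 ± 1.13) and Nav1 (−9.62 ± 1.17). P2ry13 lies within Med12l on the other strand, and a library without strand does not separate reads of the pair.

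Among the further lists from ALP to EILP, the erythroid and megakaryocyte list passed with a median of 2.93 and a mean of 3.02 (limma camera adjusted p = 0.000505, adjusted p = 0.281 with an estimated correlation) with 1 of 13 members higher and 2 adjusted over the list alone. The member past the threshold over all genes was Itga2b, the integrin chain CD41, at 5.99 ± 0.59 in EILP and the zero level in ALP. Glycolysis genes passed with a median of 0.19, 1 of 14 higher and 2 adjusted over the list alone (limma camera adjusted p = 0.0089, adjusted p = 0.332 with an estimated correlation). The aldolase gene Aldoa rose by 1.14 ± 0.13. Among lists that did not pass, 2 of 12 ILC3 and LTi genes rose and 1 fell, also adjusted over the list alone (limma camera adjusted p = 0.136). Of 10 Notch target genes 1 rose and 2 fell, 1 and 3 adjusted over the list alone (limma camera adjusted p = 0.157). Of the 6 E and Id protein genes Id2 rose and Tcf4, an E protein, fell by 1.76 on the log2 scale (limma camera adjusted p = 0.109 for the list), with 3 higher and 1 lower adjusted over the list alone. The dendritic cell list had 1 of 15 higher and Siglech, a lectin of plasmacytoid dendritic cells, lower with a change of −8.45 ± 1.43 (2 and 4 adjusted over the list alone). The list had a median of 0.86, a mean of −0.50 and a limma camera adjusted p of 0.785. In the myeloid and granulocyte list Cebpe, a granulocyte differentiation factor, rose by 4.82 ± 1.02 and was the only member of 16 to pass, also adjusted over the list alone (limma camera adjusted p = 0.169 for the list). Cytokine receptor genes had 3 of 22 higher and 3 lower (3 and 4 adjusted over the list alone), a median of −0.25, a mean of 0.43 and a limma camera adjusted p of 0.955. Without the 4 sorting markers 1 of 18 was higher and 2 lower. Chemokine receptor and adhesion genes had 4 of 17 higher and 2 lower, or 5 and 6 adjusted over the list alone (limma camera adjusted p = 0.346), and 2 of 15 higher and 2 lower without the sorting markers. Among 18 immediate early and stress genes 1 rose and 1 fell, or 2 and 1 adjusted over the list alone. They had a median of 0.09, a mean of −0.11 and a test directed upward (limma camera adjusted p = 0.733). Of 15 apoptosis regulators Bcl2 rose by 1.83 ± 0.25 and Casp8 fell by 0.63 on the log2 scale, the same 2 adjusted over the list alone. The list had a median of −0.10 that turned sign with median centring, a mean of 0.43 and a limma camera adjusted p of 0.463. None of the 85 ribosomal protein genes (median 0.00, mean −0.01, limma camera adjusted p = 0.955) and none of the 25 mitochondrially encoded genes (limma camera adjusted p = 0.194) passed, over all genes or adjusted over the list alone.

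Over all genes, 939 differed between EILP and ALP (limma adjusted p below 0.05), 419 higher and 520 lower in EILP. With each library centred on its median the split was 804 higher and 395 lower. Of the 939, 853 (90.8%) had the same sign in all 4 batches holding both groups, which their selection in the same libraries favours. Their median absolute change was 1.85, 1.87, 1.62 and 2.31 on the log2 scale within batches 1, 2, 4 and 5. In 138 of them ALP or EILP, whichever was lower, lay at the zero level. Of the 51 named genes that passed, 50 did so without each library in turn, and 23 did so under every other setting as well. In batch 5 alone 27 calls were lost, among them Tcf7 (13.55), Rora (8.51), Rag1 (−3.75), Il7r (−0.83) and Ets1 (−0.57). Without batch 4 and with only the groups compared, Ets1, Il7r, Rag1 and Ikzf2 were lost, at −1.79, −2.08, −6.63 and 3.58 without batch 4. Blk (−7.85), Cdk1 (−0.80) and Vpreb2 were also lost without batch 4, Rag1, Ikzf2 and Cebpe (4.36) without ALP 7 and EILP 2 together, and Cdk1, Cdc20 and Casp8 with median centring (−0.58, −0.55 and −0.42). A required change of at least 2-fold ended the calls of these 3 genes and Kit. Thy1 (2.91 ± 0.80, limma adjusted p = 0.0479) was lost without ALP 1, 2, 3, 6 or 7, EILP 1, 2, 6 or 7 or ILCp 1, 2, 3 or 4, with log2 fold changes of 2.54 to 3.14, and under 6 of the settings, with 2.27 to 3.42. The glycolysis list was lost without ALP 4 (limma camera adjusted p = 0.0757) or EILP 2 (adjusted p = 0.0612).

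The comparison of ILCp with EILP addressed the second step. Some genes of helper ILC subsets rose, and some myeloid and granulocyte genes fell. Of 14 ILC2 genes 5 rose and none fell, 9 adjusted over the list alone, with a median of 3.10 (limma camera adjusted p = 9.75e-10, adjusted p = 0.0174 with an estimated correlation). Of 12 ILC3 and LTi genes 3 rose and none fell, 6 adjusted over the list alone, with a median of 4.24 (limma camera adjusted p = 4.88e-05, adjusted p = 0.0174 with an estimated correlation). Of 16 myeloid and granulocyte genes 4 fell and none rose, 6 adjusted over the list alone (limma camera adjusted p = 1.06e-05, adjusted p = 0.211 with an estimated correlation). Of 100 groupings of the 19 libraries, the real one included, 19 gave at least 10 passing lists at this step. Such groupings divide the real groups unevenly, so their counts can hold real differences as well as chance. Chance is not excluded for the number of passing lists.

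Icos, the inducible costimulator of ILC2 and T cells, rose by 6.93 ± 1.25 to 7.63 ± 1.02 in ILCp (limma adjusted p = 0.00709). The lymphotoxin genes Lta (chromosome 17, 35203165 to 35205351) and Ltb (chromosome 17, 35194439 to 35196320), used by lymphoid tissue inducer cells, rose by 7.79 ± 1.48 and 5.98 ± 1.37. Cxcr6, a chemokine receptor of ILC precursors (chromosome 9, 123806475 to 123811760, within Fyco1 on the other strand), rose by 10.74 ± 2.17 to 9.51 ± 0.81 (limma adjusted p = 0.0141). Of the innate lymphoid factors 4 of 14 rose and 1 fell, with 6 and 2 adjusted over the list alone (limma camera adjusted p = 0.00214, adjusted p = 0.148 with an estimated correlation). Ets1 rose by 4.81 ± 0.44 to 10.31 ± 0.49 (limma adjusted p = 1.97e-05), Bcl11b by 3.75 ± 0.54 to 8.14 ± 0.46, Gata3 by 2.96 ± 0.46 to 10.06 ± 0.60 and Id2 by 1.53 ± 0.28. Nfil3 fell by 2.36 on the log2 scale to 5.83 ± 0.73 (limma adjusted p = 0.00501). Among the 9 factors that did not pass were Tcf7 (−1.28 ± 1.41), Tox (0.74 ± 0.29), Zbtb16 (−0.49 ± 1.12) and Rora (2.99 ± 1.11). Outside this list the fixed genes Tbx21 (4.21 ± 1.83), Flt3 (−4.09 ± 1.41), Rag1 (1.34 ± 1.81) and Il1rl1 (5.19 ± 1.74) did not pass.

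The 4 members of the myeloid and granulocyte list that fell in ILCp were Mpo, Prtn3, Cebpe and Csf3r. Mpo, the myeloperoxidase of neutrophil precursors, changed by −3.33 ± 0.83 from 11.81 ± 0.94 in EILP, Prtn3, proteinase 3, by −3.20 ± 0.71, and Cebpe by −6.50 ± 1.20 (limma adjusted p = 0.00847). Csf3r, which was named after its values were seen, changed by −6.72 ± 1.73 (limma adjusted p = 0.0463). The granule genes Elane (−5.17 ± 2.21, limma adjusted p = 0.247) and Ctsg (−5.33 ± 1.55, limma adjusted p = 0.0765) did not pass. Among the 5 largest decreases over all well expressed genes, 3 were eosinophil granule genes. Prg2, the major basic protein (chromosome 2, 84980461 to 84983632), was at 6.92 ± 3.91 in EILP and −5.67 ± 1.59 in ILCp (limma adjusted p = 0.0116). Prg3 (chromosome 2, 84988215 to 84993886) was at 3.75 ± 3.18 and −5.36 ± 1.44. Epx, the eosinophil peroxidase (chromosome 11, 87864000 to 87875536), was at 4.88 ± 3.51 in EILP and the zero level in ILCp. Prg2 was unevenly spread over the EILP libraries, at 13.1 log2 CPM in EILP 6, between 6.16 and 8.58 in EILP 1 to 5 and at −0.13, the zero level of its batch, in EILP 7. The elastase gene Elane was at 14.7 log2 CPM in EILP 2 and between 6.42 and 9.66 in the other EILP libraries. The marker S100a8 of mature neutrophils lay at least 4.97 log2 units below Mpo in each EILP library. The mean of the neutrophil genes S100a8, S100a9, Ngp and Ltf was 6.79 log2 CPM in EILP 6, the library highest for Prg2, and between −2.69 and 2.56 in the other EILP libraries. The remaining large decreases were in Ctnnd2, a catenin (3.60 ± 0.63 in EILP), and Sorcs2, a sorting receptor (3.23 ± 2.41 in EILP), both at the zero level in ILCp. The largest increases after Cxcr6 were in the calcium channel gene Cacna1e (chromosome 1, 154390731 to 154884501, 10.13 ± 0.80), Xkrx (9.96 ± 1.72), the aquaglyceroporin gene Aqp3 (9.81 ± 1.75) and Stab2, a scavenger receptor (9.60 ± 1.35). In EILP 1, 2, 6 and 7 Cacna1e and Aqp3 tied with ALP libraries at the zero level of their batch, so the folds of both genes depend on that level. Xkrx overlaps Nox1 on the same strand, so reads of the pair may have been counted for either.

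In the chemokine receptor and adhesion list 5 of 17 were higher and none lower, 7 adjusted over the list alone (limma camera adjusted p = 0.000231, adjusted p = 0.0707 with an estimated correlation, or adjusted p = 0.0264 with it when the sorting markers were left out). The chemokine receptor gene Ccr2 rose by 2.99 ± 0.53 and the integrin gene Itgal by 1.37 ± 0.23. Cytokine receptor genes had 6 of 22 higher and 2 lower, 9 and 4 adjusted over the list alone (limma camera adjusted p = 0.0577), and without the sorting markers 4 of 18 higher and 2 lower (limma camera adjusted p = 0.148). The common γ chain gene Il2rg rose by 1.75 ± 0.27 and Il21r changed by −1.56 ± 0.34. No T lineage gene of 16 passed and 1 rose adjusted over the list alone, while the list passed upward (limma camera adjusted p = 0.00847, adjusted p = 0.351 with an estimated correlation). Nfkbia, which encodes an inhibitor of NF-κB, was the immediate early and stress gene of 18 that rose (0.66 ± 0.17, limma adjusted p = 0.0488), 2 adjusted over the list alone (limma camera adjusted p = 0.0268, adjusted p = 0.351 with an estimated correlation). Of 23 cell cycle genes E2f1 (−0.86 ± 0.18) and the replication helicase gene Mcm7 (−0.63 ± 0.16) fell, and 3 fell adjusted over the list alone (limma camera adjusted p = 0.0372, adjusted p = 0.408 with an estimated correlation). Ribosomal protein genes had a median of −0.42, 1 of 85 lower, Rps2 with a change of −0.53 ± 0.11, and 28 lower adjusted over the list alone (limma camera adjusted p = 3.42e-10, adjusted p = 0.408 with an estimated correlation). Mitochondrially encoded genes had a median of −0.45 with none of 25 past the threshold, also adjusted over the list alone (limma camera adjusted p = 0.00182, adjusted p = 0.195 with an estimated correlation).

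Other lists did not pass at this step. In the lymphoid progenitor list Mef2c, a MADS-box factor, fell by 1.33 on the log2 scale as 1 of 16 (2 adjusted over the list alone, list median −0.26, mean 0.05, limma camera adjusted p = 0.431). In the stem and multipotent progenitor list 1 of 12 rose (2 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 0.254). None of 15 B lineage genes passed and 1 rose adjusted over the list alone (median −0.38, mean 0.22, limma camera adjusted p = 0.841). Of 17 NK cell and ILC1 genes 1 rose, also adjusted over the list alone (limma camera adjusted p = 0.0577), and the list passed upward without Il2rb (adjusted p = 0.0447, adjusted p = 0.305 with an estimated correlation). In the dendritic cell list Xcr1, a chemokine receptor, rose by 8.09 ± 1.57, 1 more gene rose and Irf8, a factor of dendritic cells and monocytes, fell by 2.18 on the log2 scale, the same numbers adjusted over the list alone (limma camera adjusted p = 0.508). Notch target genes had 2 of 10 higher, also adjusted over the list alone. Of 6 E and Id protein genes Id2 rose, with 2 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.33 for each list). The E and Id protein genes had a median of 0.17 and a mean of −0.58. None of 13 erythroid and megakaryocyte genes and none of 14 interferon-stimulated genes passed, over all genes or adjusted over the list alone (limma camera adjusted p = 0.841 and 0.143). Of 14 glycolysis genes 1 rose, with 3 higher and 3 lower adjusted over the list alone (limma camera adjusted p = 0.841). None of 15 apoptosis regulators passed, with 2 higher and 2 lower adjusted over the list alone (limma camera adjusted p = 0.834). The median of the apoptosis regulators was 0.04, which turned sign with median centring and with quantile normalization, and their mean −0.10.

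In all, 598 genes differed between ILCp and EILP (limma adjusted p below 0.05), 327 higher and 271 lower in ILCp. With median centring the split was 279 higher and 390 lower. The same sign held in all 3 batches with both groups for 569 of them (95.2%), again favoured by the selection, with median absolute changes of 1.46, 1.56 and 1.48 within batches 1, 2 and 4. This count moved with single libraries: it was 224 without EILP 5, 316 without ILCp 2, 355 without EILP 2 and 384 without ILCp 1, and 254 without the Plzf-cre-GFP libraries. Of the 36 named genes that passed, 13 did so without each library in turn, and of these Bcl11b, Ets1, Cacna1e, Stab2 and Ctnnd2 did so under every other setting as well. Of the other 8, Icos and Aqp3 were lost without the Plzf-cre-GFP libraries (6.72 and 9.30), without batch 4 (7.21 and 9.02) and with only the groups compared (7.67 and 8.72). Nfil3 (−2.39), Gata3 (2.58), Cebpe (−6.50) and E2f1 (−0.88) were lost in batches holding both groups, Il2rg (1.74) and E2f1 (−0.89) with only the groups compared, and Il7r (4.38) without batch 4. Among the 23 genes lost without some library, 22 were lost without EILP 5, the only EILP library of batch 4, and 11 without ILCp 2. Those lost without EILP 5 alone then had log2 fold changes of 1.14 in Id2, 4.38 in Thy1, 7.33 in Lta, 9.50 in Cxcr6, 2.55 in Ccr2, 1.17 in Itgal, 7.91 in Xcr1, −0.49 in Rps2, −12.61 in Prg2 and 9.22 in Xkrx, and Epx was lost likewise. Il21r was also lost without EILP 1 or ILCp 2 (−1.67 to −1.32) and Prg3 without EILP 1, EILP 2 or ILCp 2 (−9.21 to −8.51). Irf8 was lost without EILP 1 to 5 or ILCp 1 or 2 (−2.30 to −1.91), and Ltb without ALP 4, EILP 3, 4 or 5 or ILCp 1, 2 or 5 (5.00 to 6.58), while without EILP 2 it kept its call at 3.87. Leaving out EILP 3 or EILP 4 changes the error alone and not the fold change. Kit (0.48 ± 0.12) was lost without EILP 2, 5, 6 or 7 or ILCp 1, 2, 4 or 5 (0.41 to 0.49), and Prtn3 without EILP 2, 3 or 4 or ILCp 1, 2 or 5 (−3.20 to −2.44). Only ALP 6 or 7 could be left out with Mcm7 kept (−0.70 to −0.57 when lost), only ALP 4 or ILCp 3 or 4 with Mpo kept (−4.21 to −2.15, the smallest change without ILCp 2), and only ILCp 3 or 4 with Csf3r kept (−7.49 to −5.21). Mef2c was kept without ALP 1 or 7, EILP 2 or 6 or ILCp 4 and lost without any other library (−1.48 to −1.13), and Sorcs2 was kept only without ALP 2, 3 or 5, EILP 1 or ILCp 1. Nfkbia was kept only without EILP 7 or ILCp 2 (0.57 to 0.69 when lost), and was lost with quantile normalization (0.63) and median centring (0.57). T lineage genes were lost without ILCp 1 or 2 (limma camera adjusted p = 0.0583 and 0.111). Immediate early and stress genes were lost without EILP 5, EILP 6 or ILCp 1 (0.184, 0.0513 and 0.104), and cell cycle genes without ALP 6, EILP 5 or 6 or ILCp 2 or 5 (0.0554 to 0.0722).

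The comparison of ILCp with ALP spanned both steps. Innate lymphoid factors and genes of NK cells, ILC2 and ILC3 were higher in ILCp, and lymphoid progenitor and cell cycle genes were lower. Of the 14 factors 11 rose and none fell, with 11 higher and 1 lower adjusted over the list alone and a median of 7.14 (limma camera adjusted p = 4.92e-22, adjusted p = 0.000215 with an estimated correlation). Gata3 rose by 8.51 ± 0.44, Id2 by 6.11 ± 0.27, Tox by 4.91 ± 0.28, Rora by 10.32 ± 1.07, Zbtb16 by 8.88 ± 1.08 and Ets1 by 3.04 ± 0.42 (limma adjusted p = 0.000241), while Nfil3 was 0.60 ± 0.39 apart (limma adjusted p = 0.415). Bcl11b was at the zero level in ALP and at 8.14 ± 0.46 in ILCp. Zbtb16 encodes PLZF, which the green gate read in the Plzf-cre-GFP libraries, so its level there is in part set by the sort.

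NK cell and ILC1 genes had 11 of 17 higher and none lower, also 11 adjusted over the list alone (limma camera adjusted p = 3.69e-09, adjusted p = 0.00569 with an estimated correlation). Ccl5 rose by 11.08 ± 0.95, the lectin receptor gene Klrb1b by 10.87 ± 1.54 and Tbx21 by 7.55 ± 1.77 (limma adjusted p = 0.0139). Of 14 ILC2 genes 8 rose, 11 adjusted over the list alone (limma camera adjusted p = 3.83e-13, adjusted p = 0.00349 with an estimated correlation). Arg1, the arginase of ILC2 and their precursors, was at 7.09 ± 1.39 in ILCp and the zero level in ALP. Il1rl1 did not pass (4.42 ± 1.68, limma adjusted p = 0.132). Of 12 ILC3 and LTi genes 6 rose and 1 fell, 8 and 1 adjusted over the list alone (limma camera adjusted p = 5.41e-07, adjusted p = 0.00349 with an estimated correlation). Cxcr5 rose by 8.76 ± 0.99 and Cxcr6 by 13.95 ± 2.09. T lineage genes had 5 of 16 higher, or 7 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 5.50e-06, adjusted p = 0.0579 with an estimated correlation). Themis was at 5.65 ± 0.98 log2 CPM in ILCp and the zero level in ALP. Chemokine receptor and adhesion genes had 7 of 17 higher and 2 lower, 8 and 3 adjusted over the list alone (limma camera adjusted p = 8.19e-05, adjusted p = 0.0237 with an estimated correlation). Without the sorting markers 5 of 15 were higher and 2 lower (limma camera adjusted p = 0.00318, adjusted p = 0.0701 with an estimated correlation). Ccr2 rose by 4.87 ± 0.51 and Cxcr4, the receptor that keeps progenitors in marrow, changed by −1.68 ± 0.31. Cytokine receptor genes had 9 of 22 higher and 5 lower, 11 and 7 adjusted over the list alone (limma camera adjusted p = 0.0328, adjusted p = 0.0579 with an estimated correlation). Without the 4 sorting markers 6 of 18 were higher and 4 lower, and the list did not pass (limma camera adjusted p = 0.185). Il2rg rose by 2.10 ± 0.26 and Il21r changed by −2.63 ± 0.33.

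**Figure D2:**
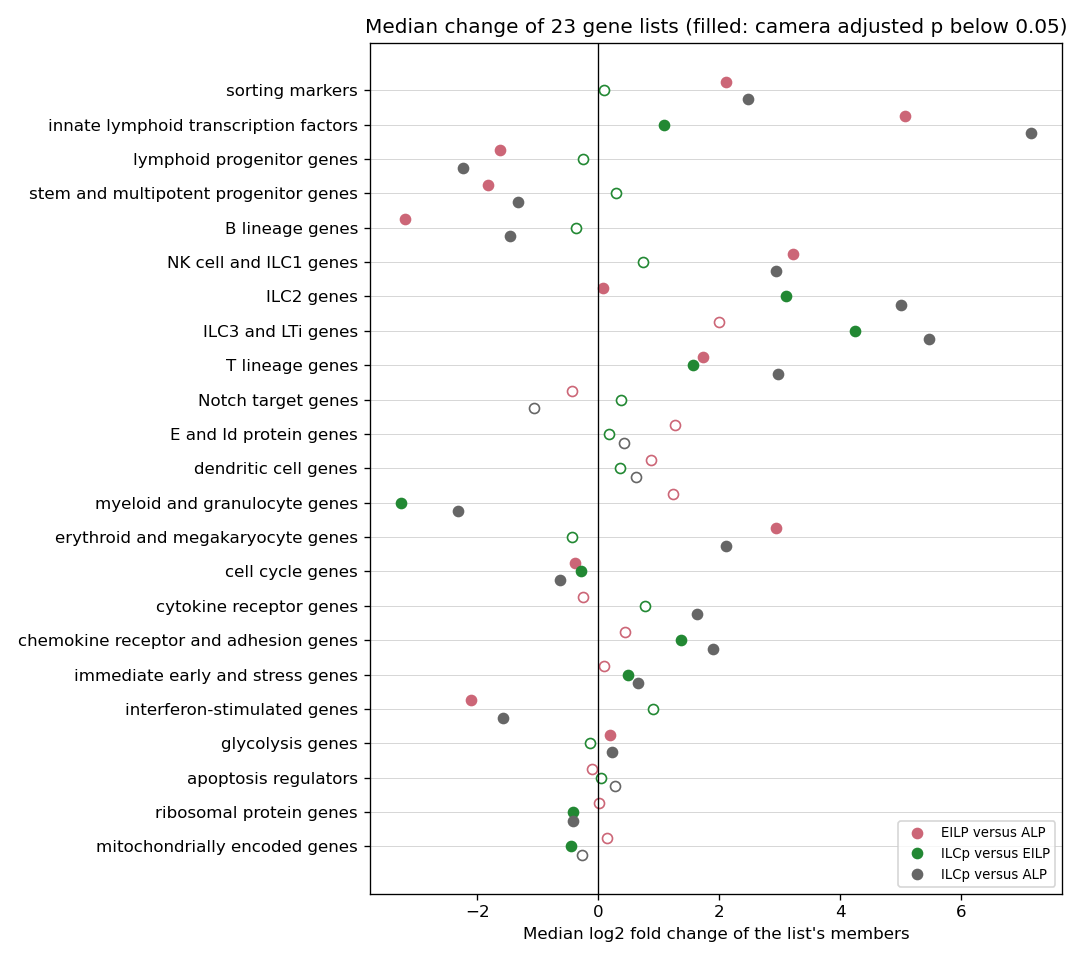
Median log2 fold change of the members (horizontal axis) of each of 23 gene lists (vertical axis) in the 3 comparisons, with filled points for lists with a limma camera adjusted p below 0.05. Innate lymphoid factors had medians of 5.07 in EILP versus ALP and 7.14 in ILCp versus ALP, and 4 of 16 myeloid and granulocyte genes were lower in ILCp than in EILP, a list that did not pass with an estimated correlation (adjusted p = 0.211).

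Lower in ILCp than in ALP were 12 of 16 lymphoid progenitor genes, against 1 higher (13 and 1 adjusted over the list alone, limma camera adjusted p = 6.44e-10, adjusted p = 0.0112 with an estimated correlation). Mef2c changed by −2.80 ± 0.31 and Cd93 by −1.97 ± 0.25. Rag1 did not pass (−5.71 ± 1.75, limma adjusted p = 0.0566). Of 23 cell cycle genes 13 fell, 17 adjusted over the list alone (limma camera adjusted p = 3.69e-09, adjusted p = 0.0199 with an estimated correlation). Cdk1 changed by −1.22 ± 0.19 and Cdc20 by −1.06 ± 0.18. In the stem and multipotent progenitor list 2 of 12 fell, 3 adjusted over the list alone, with the homeobox gene Hoxa9 changed by −4.20 ± 0.64 (limma camera adjusted p = 0.0419 for the list, adjusted p = 0.232 with an estimated correlation). B lineage genes had 5 of 15 lower, 6 adjusted over the list alone (limma camera adjusted p = 0.0015, adjusted p = 0.226 with an estimated correlation). The B cell linker gene Blnk changed by −9.03 ± 2.00. Interferon-stimulated genes had 5 of 14 lower, 6 adjusted over the list alone (limma camera adjusted p = 0.000308, adjusted p = 0.0579 with an estimated correlation). Bst2, which encodes tetherin, changed by −1.44 ± 0.22. Myeloid and granulocyte genes had 2 of 16 lower, also adjusted over the list alone (limma camera adjusted p = 0.00214, adjusted p = 0.283 with an estimated correlation). The G-CSF receptor gene Csf3r changed by −7.04 ± 1.67, and S100a8 reached 5.30, 9.94 and 7.93 log2 CPM in ALP 1, 2 and 6. Ribosomal protein genes had 7 of 85 lower, 9 adjusted over the list alone, with a median of −0.42 (limma camera adjusted p = 3.69e-09, adjusted p = 0.315 with an estimated correlation). Rps2 changed by −0.48 ± 0.10.

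Upward shifts passed in 3 further lists and in the sorting markers. Immediate early and stress genes had 3 of 18 higher, also adjusted over the list alone (limma camera adjusted p = 0.0163, adjusted p = 0.226 with an estimated correlation). The antiproliferative gene Btg2 rose by 1.76 ± 0.30 and Junb by 1.58 ± 0.28. Glycolysis genes had 4 of 14 higher, or 5 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.0419, adjusted p = 0.377 with an estimated correlation). Aldoa rose by 1.31 ± 0.15. Of 13 erythroid and megakaryocyte genes 1 rose, also adjusted over the list alone, with a list median of 2.10 (limma camera adjusted p = 0.00309, adjusted p = 0.315 with an estimated correlation). Sorting markers had 7 of 9 higher and 1 lower, 7 and 2 adjusted over the list alone (limma camera adjusted p = 2.16e-06, adjusted p = 0.00745 with an estimated correlation). Kit rose by 1.17 ± 0.11. Among lists that did not pass, 3 of 10 Notch target genes rose and 3 fell, also adjusted over the list alone (median −1.07, mean 0.50, limma camera adjusted p = 0.731). Of the 6 E and Id protein genes Id2 rose and Tcf4 fell, by 1.40 on the log2 scale, with 2 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.0935). Dendritic cell genes had 2 of 15 higher and 3 lower, 5 and 5 adjusted over the list alone, with a change of −2.88 ± 0.47 in Irf8. They had a median of 0.62, a mean of −0.23 and a limma camera adjusted p of 0.616. Of 15 apoptosis regulators 2 rose and 2 fell, also adjusted over the list alone (limma camera adjusted p = 0.298), with changes of 2.15 ± 0.28 in Bcl2 and −0.81 ± 0.13 in Casp8. None of 25 mitochondrially encoded genes passed, over all genes or adjusted over the list alone (limma camera adjusted p = 0.0725).

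The largest increases from ALP to ILCp were in Cxcr6, in the Ikaros family gene Ikzf3 (8.36 ± 1.08 in ILCp), and in Tcrg-C4, Rxrg and Bcl11b, with Tcrg-C4 at 9.06 ± 0.42 and Rxrg at 8.56 ± 0.73 in ILCp. ALP lay at the zero level for Ikzf3, Tcrg-C4, Rxrg and Bcl11b, so their rank depends on that level. Segments of the T cell receptor loci were raised beyond the constant genes: 10 of 13 joining segments of the β locus and 3 of 3 of the γ locus rose from ALP to ILCp. So did 3 of 16 and 4 of 7 variable segments and 1 of 4 genes of the δ locus, whereas 0 of 18 variable segments of the α locus passed. The mean of Cd3d, Cd3e, Cd3g, Cd5 and Trac was at least 8.53 log2 units below Trbc1 in each ILCp library, although Cd3d and Cd3g themselves rose from ALP, to 0.62 ± 1.55 and 1.99 ± 3.68 log2 CPM (limma adjusted p = 0.0209 and 0.0370). The largest decreases were in Cd33, a lectin of myeloid cells (chromosome 7, 43524216 to 43544428, −11.70 ± 1.34), the monoamine transporter gene Slc18a1 (−10.45 ± 1.43), Siglech (−10.10 ± 1.64), the ephrin receptor gene Ephb2 (−9.97 ± 1.54) and Rgs8, which was at 4.24 ± 1.17 in ALP and at the zero level in ILCp.

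Altogether 1534 genes differed between ILCp and ALP (limma adjusted p below 0.05), 718 higher and 816 lower in ILCp, and 813 higher and 584 lower with median centring. All 3 batches with both groups gave the same sign for 1471 of them (95.9%), likewise favoured by the selection, with median absolute changes of 1.8, 2.06 and 1.69 within batches 1, 2 and 4. Without ILCp 2 the count was 920, and without the Plzf-cre-GFP libraries it was 1012. Of the 47 named genes that passed, 44 did so without each library in turn, and 36 did so under every other setting as well. Without batch 4, Tcf7 (8.75), Il7r (2.30), Tcf4 (−1.33), Cxcr6 (13.33) and Rps2 (−0.42) were lost. Il7r (2.31) and Rps2 (−0.44) were lost without the Plzf-cre-GFP libraries, Flt3 (−6.55) and Irf8 (−2.86) with only the groups compared, and Il7r (2.05) and Flt3 (−6.71) in batches holding both groups. Rps2 was also lost with median centring (−0.35) and without trend, and Rps2 and Casp8 with a required change of at least 2-fold. Blnk was lost without ALP 4 or ILCp 1, Csf3r without ILCp 1 or 2 and Tbx21 without ILCp 2, with log2 fold changes of −8.72 to −7.26, −6.77 to −5.36 and 6.58. Lists were lost as follows with limma camera: B lineage genes without ALP 1 (adjusted p = 0.0908), and myeloid and granulocyte genes and erythroid and megakaryocyte genes without ILCp 2 (0.157 and 0.212). Immediate early and stress genes were lost without ALP 1 or ILCp 1 (0.210 and 0.0512), and cytokine receptor genes without ALP 4, EILP 5 or ILCp 3 or 5 (0.0525 to 0.0854). Glycolysis genes were lost without ALP 4 or 6, EILP 1 or 2 or ILCp 3 or 4 (0.0517 to 0.299). Stem and multipotent progenitor genes were lost without ALP 2, 4, 5 or 6, EILP 1, 2, 3, 4, 5 or 7 or ILCp 4 (0.0534 to 0.149).

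Genes with their extreme level in EILP were those past the threshold in opposite directions at the 2 steps. There were 34 genes highest in EILP and 51 lowest in EILP. The 5 with the largest changes at both steps among those highest were the collagen genes Col1a1 (chromosome 11, 94936224 to 94953042) and Col1a2 (chromosome 6, 4504814 to 4541544), the dehydrogenase gene Dhrs2, the carboxypeptidase gene Cpb1 and Flt1, a VEGF receptor. Col1a1 was at 5.23 ± 3.43 and Col1a2 at 5.55 ± 3.13 in EILP, with Col1a1 between 2.89 and 9.43 in EILP 2 to 7 and at the zero level of its batch in EILP 1. Over the EILP libraries the mean of 19 other genes of bone stroma followed the mean of both collagens (Pearson r = 0.888, permutation p = 0.00476), although Postn lay at the zero level in all 7 EILP libraries and Serpinf1 was at 6.07 ± 0.52 in EILP and 6.39 ± 0.43 in ALP. The permutation p is descriptive, because batch removal ties the values of the EILP libraries to each other. In ALP, Col1a2 was at −3.82 ± 2.06, and in ILCp at −2.86 ± 2.54, and Col1a1 lay at the zero level in both. Dhrs2 was at 3.41 ± 0.81 in EILP and the zero level in ALP, Cpb1 at 1.34 ± 2.62 in EILP and the zero level in ALP and ILCp, and Flt1 at 1.62 ± 1.34 in EILP and the zero level in ILCp. Regulators with the same course were Nfil3, Mycn (7.69 ± 0.20 in EILP against 5.13 ± 0.73 in ALP and 5.92 ± 0.48 in ILCp), the cell cycle inhibitor Cdkn1a, Nfkb1 and Cebpe. The chaperone genes Calr and Hspd1 were also among the 34. All of these but Nfil3 and Cebpe were chosen after their values were seen.

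The 5 leading genes lowest in EILP were Sdc1, a heparan sulfate proteoglycan (7.15 ± 1.66 in ALP, 0.10 ± 2.32 in EILP, 7.22 ± 1.16 in ILCp), the ribonuclease gene Rnase4, Klhl4, the T cell adaptor gene Sh2d2a and Il17re, a receptor of the IL-17 family (6.03 ± 1.56, −0.61 ± 2.35 and 5.44 ± 0.97). Ets1, Il7r, Ly6a and Tgfbr2, a TGF-β receptor (6.38 ± 0.30, 5.14 ± 0.25 and 8.20 ± 0.41), took the same course, the last chosen after its values were seen. At both steps 24 genes rose, including Gata3, Id2, Bcl11b and Ccr2, and 13 fell, including Runx2, Mef2c and Il21r. Independent calls would give 6.10 genes highest, 9.14 lowest, 7.36 rising at both steps and 7.57 falling at both. Unchanged groups that share the EILP libraries gave 0 in each class in 50 simulations. None of the simulations had calls at both steps, so the classes were 0 by construction and give no measure of chance. With the EILP libraries divided between the steps, 414 and 14 genes passed. Independent calls would then give 0.0221 highest, 0.134 lowest, 0.133 rising and 0.0224 falling, against 0, 0, 3 and 0 found. With 14 genes at the second step the classes can hardly be compared, and part of the excess may come from the shared libraries. The log2 fold changes of the steps had a covariance of −0.682 across genes, which are not independent replicates, against −0.502 in the simulations, a difference of −0.18. With the EILP libraries divided the covariance was 0.0799 and the correlation 0.0237, against a correlation of −0.286 with the libraries shared and −0.462 in the simulations. Genes highest in EILP numbered 22 without ALP 4, 22 without EILP 2, 17 without EILP 5 and 15 without the Plzf-cre-GFP libraries. Genes lowest in EILP numbered 31 without ALP 4, 29 without EILP 5, 29 without ILCp 2 and 23 without the Plzf-cre-GFP libraries.

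**Figure D3:**
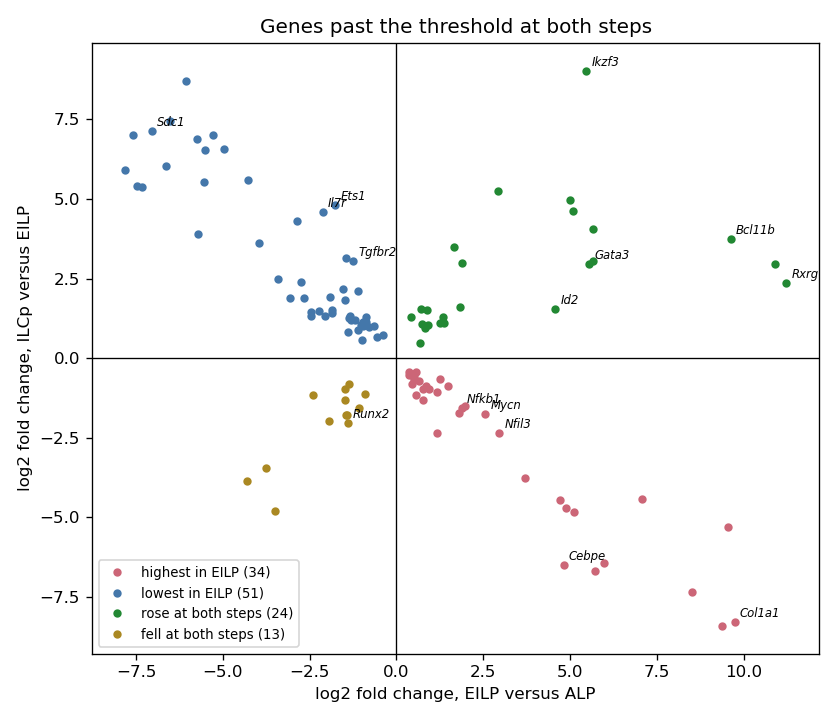
Log2 fold change of EILP versus ALP (horizontal axis) against that of ILCp versus EILP (vertical axis) for genes past the limma threshold at both steps (points), coloured by class. The 51 genes lowest in EILP lie at the upper left, the 34 highest in EILP at the lower right, the 24 that rose at both steps at the upper right and the 13 that fell at both at the lower left, and positions of genes at the zero level in a group depend on that level.

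The ILCp libraries from the reporter strains, 2 from Plzf-cre-GFP mice and 3 from Tcf7EGFP mice, were compared. The green gate read PLZF in the first and Tcf7 in the others, so strain and gate cannot be told apart. Between the 2 sets of libraries 14 genes differed (limma adjusted p below 0.05), 12 higher and 2 lower in Plzf-cre-GFP ILCp. Of the 14, 13 lay at the zero level in at least 10 of the 19 libraries. The 5 leading genes higher in the Plzf-cre-GFP libraries were Vipr1 (0.14 ± 0.87 log2 CPM), Pacsin3 (0.09 ± 0.58), Ogdhl (−0.17 ± 1.65), Noxa1 (−0.31 ± 0.37) and Hoga1 (−0.41 ± 1.32), all near or below 1 CPM. Hnf4a, a nuclear receptor, was at 2.50 ± 0.19 in the Tcf7EGFP libraries. Both Plzf-cre-GFP libraries lay at −2.81, the zero level of batch 4 for this gene, so the size of the difference depends on that level. Within batch 4, which held both Plzf-cre-GFP libraries, Hnf4a was at 2.32 in ILCp 3. RP24-87I22.4 was the other gene that was lower. The count was 26, 24 and 50 without ILCp 1, 2 and 3. Without ILCp 4 or 5 it was 236 and 134, but the Plzf-cre-GFP arm then held 1 library, which was assumed to vary like the other groups.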

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

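The tests of T cells, shared constant-gene reads, mature neutrophils and granulocyte precursors were chosen after the result was seen, and the groupings were set down beforehand. The stromal prediction was written before its test was run. The collagens came from the genes highest in EILP in these same libraries, and the stromal genes were chosen after their values were seen. Its p-value is therefore not that of a test planned before the data.

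Most constant and joining segments of the T cell receptor β and γ loci rose in EILP and ILCp. Of the β variable segments 2 of 16 rose from ALP to EILP and 3 of 16 from ALP to ILCp. The α variable segments did not pass, and 1 of 4 genes of the δ locus rose from ALP to ILCp. T cells in the gate would bring their other abundant transcripts, but the mean of Cd3d, Cd3e, Cd3g, Cd5 and Trac relative to Trbc1 was at most −8.53 log2 units over the ILCp libraries and −5.20 over the EILP libraries, and the lineage-low, Kit-positive gate would remove most of these cells. T cells therefore do not account for the level of Trbc1, but Cd3d and Cd3g also rose from ALP to ILCp (to 0.62 and 1.99 log2 CPM), and a small number of T cells is not excluded. Reads shared between near-identical constant genes would leave joining segments unmoved, but 81.25% of the joining segments of both loci rose from ALP to ILCp. Transcription of unrearranged loci in these progenitors may remain as an explanation, and no biological explanation was tested.

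The granule genes Mpo, Prtn3, Prg2, Prg3 and Epx were lower in ILCp than in EILP, while Elane and Ctsg did not pass (limma adjusted p = 0.247 and 0.0765). If mature neutrophils were the source of Mpo, S100a8 would lie at or above it. S100a8 was at most −4.97 log2 units from Mpo in the EILP libraries (2.66 to 7.30 against 10.30 to 13.14 log2 CPM), so neutrophils do not account for Mpo, and the same gate would remove most of them. With Mpo this high, the comparison cannot tell whether some neutrophils were present. In EILP 6, the library highest for Prg2, the mean of S100a8, S100a9, Ngp and Ltf stood apart at 6.79 log2 CPM against −2.69 to 2.56 in the other EILP libraries, and some neutrophils there are not excluded. A high mean was not particular to EILP 6: it was 5.84, 8.86 and 7.64 in ALP 1, 2 and 6, and −3.81 to 0.49 in the other ALP libraries. Early granulocyte or eosinophil precursors within the gate may be a source, although few would carry the reporter, but the means of the eosinophil and early granule genes over the 7 EILP libraries had a Pearson r of 0.0676 (exact permutation p = 0.838, Spearman rho = 0.179, permutation p = 0.713, adjusted p = 0.838 over 2 relations), and r was −0.0124 without EILP 2 and 5. With 7 libraries, such cells and expression by EILP themselves cannot be told apart, and 1 source for both gene groups would need a closer relation.

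Collagen transcripts were detected in 6 of the 7 EILP libraries. Bone stromal cells or their RNA may have entered the EILP gate, although few would carry Kit and the reporter, and Col1a1 reached 9.43 log2 CPM in EILP 5: over the 7 libraries the mean of 19 other stromal genes followed Col1a1 and Col1a2 with a Pearson r of 0.888 (exact permutation p = 0.00476, adjusted p = 0.00952 over 2 relations, Spearman rho = 0.893, permutation p = 0.0123), and r was 0.951 without EILP 1 and 5. Of the 19 genes, 17 had an r above 0 and a higher mean in EILP than in ALP and 4 rose past the threshold, whereas Postn lay at the zero level in all 7 EILP libraries and Serpinf1 was no higher in EILP (6.07) than in ALP (6.39 log2 CPM). Batches hold too few EILP libraries for a value within each. Expression by EILP themselves stays open and was not tested.

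Random groupings of the libraries gave fewer changed genes than the real one between EILP and ALP (939, highest other 6), ILCp and EILP (598, highest other 55) and ILCp and ALP (1534, highest other 23). In each, 1 of 100 groupings was as large, the real one. The groupings mixed the libraries of all 3 groups, so real differences entered the spread within the other groupings and lowered their counts. They address whether all 3 groups are alike, and cannot give the chance rate of a single comparison. The groups were sorted on different markers, so a difference between them could be foreseen. For lists from ALP to EILP 2 of 100 groupings were as large (12, highest other 13), so another grouping passed more lists than the real one. For lists from ALP to ILCp the real grouping alone was as large (18, highest other 13). These shares were not adjusted over the counts compared. For lists from EILP to ILCp chance was not excluded (10, highest other 15, 19 of 100 as large). The other groupings passed a median of 3, 4 and 3 lists in the same order. Because they divide the real groups unevenly, real differences can enter these numbers, which do not give the rate of chance calls. Passing at the preset correlation does not by itself exclude chance for a single list. For genes highest in EILP (34, highest other 1) and lowest in EILP (51, highest other 0) the groupings decide nothing, since 1 of the 99 others had calls at both steps.

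A single library stood apart from its group, by the gap to its nearest neighbour as a share of the group's range, in 29 of 351 groups of values (8.26%) over 94 genes and 23 lists. Independent normal values would give about 1 in 20. Batch removal ties the libraries, and many of the genes were picked for their changes, so that share is only a rough reference here. In 19 of the 351 groups of values the genes lay at the zero level, and 7 of the 29 fell there, which leaves 22 of 332 (6.63%). For 6 of the 7, Fgf3, Itga2b, Themis and Eomes in ALP and Sorcs2 and Ctnnd2 in ILCp, the zero level of the batch of the library standing apart could not be read, so the gap does not separate expression from the offset left by batch removal. ALP 4 was such a library for 6 genes, as the highest for Fgf3 (0.921), Itga2b (0.781), Themis (0.767) and Eomes (0.702) and the lowest for Rgs8 (0.694) and Nfkbia (0.572). ALP 6 was lowest for Blk (0.735), Rag1 (0.679) and Notch1 (0.608), and ALP 3 highest for Irf7 (0.707). EILP 2 was lowest for Ltb (0.712) and Tox (0.56807, barely past the critical value for 7 libraries). EILP 5 was highest for Rgs8 (0.760) and Flt3 (0.664) and lowest for Id2 (0.716). EILP 7 was highest for Rag1 (0.692) and lowest for Hoxa9 (0.696) and the mean of the stem and multipotent progenitor genes (0.577). EILP 1 was highest for Ephb2 (0.601) and EILP 6 for Lta (0.571). ILCp 5 was lowest for Dntt (0.896, at 3.45 log2 CPM against 8.04 in the next library), Flt3 (0.777, at −3.47 against 3.90) and Itga2b (0.745). ILCp 1 was highest for Sorcs2 (0.855) and lowest for Tbx21 (0.714), ILCp 2 lowest for Ctnnd2 (0.869) and highest for the mean of the Notch target genes (0.901), ILCp 3 lowest for Bcl11b (0.772) and ILCp 4 lowest for Eomes (0.759).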

How the results depend on the processing

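The alternatives without batch 3, without batch 4 and without ALP 7 and EILP 2, and the lists without the sorting markers, were chosen after seeing the data. Counts of genes moved with the model and with the libraries held, and the 12, 10 and 18 passing lists became 6, 2 and 8 with an estimated correlation. The cause was not tested except where an alternative holds fewer libraries or a model without batch reads values already cleared of batch. Depth is unknown and limits what can be said of low genes. A pseudocount alternative was not run.

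Genes changed from ALP to EILP numbered 2551 with no batch term, 3391 with batch as a random effect (correlation within batch −0.24), 397 in batch 5 alone and 583 without batch 4, and 696 to 964 with 1 library left out. From EILP to ILCp they numbered 3047 with no batch term, 8201 with batch as a random effect, 183 with only the groups compared, 254 without the Plzf-cre-GFP libraries, 233 in batches with both groups, 280 without trend, 309 without ALP 7 and EILP 2, 258 without batch 4 and 224 to 624 with 1 library left out. From ALP to ILCp the counts were 3856, 11612, 772, 1012 and 855 under the first 5 of these settings, 855 without batch 4, and 920 to 1584 with 1 library left out.

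With the replicate number as a block in place of batch the counts were 1613, 1484 and 2362 in the same order, and 117 genes were highest and 134 lowest in EILP. The labels do not say that the numbers pair libraries, and they were not taken to. Correlations of same-numbered libraries were −0.640 to −0.169 for the 10 pairs within a batch, where batch removal forces them down and a shared number could not show, and −0.0323 to 0.116 for the 7 other pairs.

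Lists past the threshold were 6, 2 and 8 with an estimated correlation, 6 from EILP to ILCp without batch 4, and 11, 11 and 16 without the sorting markers. With fry they were 16, 8 and 18. From EILP to ILCp the T lineage list did not pass with fry (fry adjusted p = 0.130), and the cytokine receptor list did (fry adjusted p = 0.0018). With 1 library left out they were 11 to 13, 8 to 12 and 15 to 19. Genes highest in EILP were 297 with no batch term, 15 without the Plzf-cre-GFP libraries, 0 with the EILP libraries divided (only 14 genes then passed at the second step), 17 without ALP 7 and EILP 2, 17 without batch 4 and 17 to 40 with 1 library left out, and genes lowest in EILP were 282, 23, 0 and 10 under no batch term, no Plzf-cre-GFP libraries, divided libraries and no batch 4, and 29 to 52 with 1 library left out. Reporter genes were 6 with no batch term and 24 to 236 with 1 ILCp library left out, the highest from a Plzf-cre-GFP arm of 1 library assumed to vary like the other groups.

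Genes that had not passed turned sign in places: Il1rl1 from ALP to EILP was 2.76 in batch 5 alone and −1.58 (without EILP 7) to 0.68 (without EILP 2) with 1 library left out; Tcf7 from EILP to ILCp was 0.43 with only the groups compared and 0.32 in batches with both groups; Zbtb16 at that step was 0.57 and 0.30 under these settings, 0.080 without batch 4, and −1.18 (without EILP 5) to 0.14 (without ALP 4) with 1 library left out. Median centring moved the median of all genes to 0.22 from ALP to EILP and −0.17 from EILP to ILCp, against 0 and −0.08 as deposited.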

Other observations

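All genes in this part but Nfkbia and Hoxa9 were chosen after their values were seen.

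Further regulators changed along the sequence, and Hoxa9, Runx3, Lmo2 and Nfkbia among them are also members of the fixed lists. Of 4 homeobox genes of the Hoxa cluster, 3 fell from ALP to EILP, with log2 changes of −6.00 in Hoxa10 (limma adjusted p = 0.00240), −5.18 in Hoxa5 (limma adjusted p = 0.00514) and −2.29 in Hoxa9 (limma adjusted p = 0.0232). Hoxa7 did not pass (−1.50, limma adjusted p = 0.455). Of 3 Runx genes, Runx2 fell at both steps, with changes of −1.41 and −2.03, and Runx3, a factor of cytotoxic lymphocytes, rose from ALP to EILP by 1.65 (limma adjusted p = 0.000212) and did not pass from EILP to ILCp (−0.60, limma adjusted p = 0.258). Runx1 passed at neither step (limma adjusted p = 0.596 and 0.117). Of 3 Myc genes, Mycn rose by 2.56 and then fell by 1.76 on the log2 scale. Myc changed by −0.72 at the first step (limma adjusted p = 0.0328), a call lost with median centring (−0.51), and did not pass at the second (limma adjusted p = 0.327), while Mycl passed at the second alone, with a change of −6.86 (limma adjusted p = 0.0147, against 0.980 at the first). Of 10 genes of NF-κB and its inhibitors, 7 passed at neither step and Nfkb1 rose by 1.88 and then fell by 1.57 on the log2 scale. Nfkbiz (−5.75 and 6.88, limma adjusted p = 0.0151 and 0.0241) and Nfkbia (−0.57 and 0.66, limma adjusted p = 0.0309 and 0.0488) fell and then rose, but both calls of Nfkbia were lost with median centring (−0.36 and 0.57). Lmo4, a LIM domain protein, rose at both steps, by 1.66 and 3.49, and Lmo2, a factor of stem cells, changed by −2.44 from ALP to EILP. Of 11 genes of Stat proteins and their inhibitors, 9 did not pass at each step. From ALP to EILP Stat3 rose by 1.08 (limma adjusted p = 0.00440) and Socs2 changed by −6.75 (limma adjusted p = 0.00289). From EILP to ILCp Socs1, an inhibitor of cytokine signalling, rose by 2.66 (limma adjusted p = 0.000206) and Stat4 by 1.65 (limma adjusted p = 0.0217). Socs1 passed at the first step too with quantile normalization and with median centring (1.02 and 1.03). Pdcd1 and Cd160, which encode receptors of lymphocytes, rose from ALP to EILP by 8.18 and 6.53 (limma adjusted p = 0.00184 and 0.00268). Of 6 mast cell and basophil genes, Cpa3 rose at this step by 9.35 (limma adjusted p = 0.000253) and Alox5 by 8.58 (limma adjusted p = 2.05e-05). Hdc (5.48), Mcpt8 (3.24), Ms4a2 (2.04) and Fcer1a (−1.06) did not pass (limma adjusted p = 0.0687, 0.338, 0.560 and 0.851), although Hdc passed with median centring. No list test was run on any of these families.

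Sex-linked transcripts differed between libraries of a group. ALP 7 had Xist at 8.66 log2 CPM and a mean of Y chromosome genes of −4.31, and EILP 4 had Xist at 5.94 together with Y chromosome genes at 4.17. Within batch 4 ALP 4, EILP 5 and ILCp 5 also held both, with Xist at 3.43, 3.08 and 3.77 and Y chromosome genes at 3.89, 4.82 and 4.14, while Xist was at −7.68 in ILCp 3 and ILCp 4. In batch 2 Xist was at 0.44, −0.48 and 1.90 in ALP 2, EILP 2 and ILCp 2, against −1.83 in ALP 3, with Y chromosome genes at 5.33, 3.49, 5.55 and 3.04 in the same order. The labels used here do not give the sex of the mice.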
